A study of Arabidopsis thaliana with 11 samples.

How the data were processed

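RNA from inflorescences of Arabidopsis thaliana, ecotype Ler, was hybridised by the authors to 11 Affymetrix ATH1 arrays, a single-colour platform on which several short probes make up each probe set. Per the labels, the plants were 30 days old and the tissue held flowers of stage 12 and younger. The deposited values are log2 expression values that the authors made with the GC-RMA method, which subtracts a background predicted from probe sequence, normalizes the arrays to each other and summarises the probes of a set. Per the series design text and the submitters' processing notes this was run in R 2.7.2 with Bioconductor 2.2; settings beyond these names are not given in the sources used here. The log2 scale was checked on the values, which ran from 2.61 to 14.37, with array medians between 6.08 and 6.27. GC-RMA pulls dim probe sets towards a floor, so that fold changes of dim transcripts are compressed, and its between-array normalization assumes similar overall distributions. Scanner images and probe-level intensities were not analysed here. All value columns matched a sample by name.

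The arrays fell into 3 groups by their labels: 7 labelled wild type, 2 of the nga quadruple mutant, which carries mutant alleles of all 4 NGATHA genes, and 2 of plants that express an artificial microRNA against these genes from the viral 35S promoter (amiR-NGA). The labels do not say whether replicates came from separate plantings, so p-values measure only the spread between these samples, which may be technical. For 3 of the arrays labelled wild type the labels note long days and for the others they state no day length. The number of arrays limits the precision of every value. No columns held identical values.

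Of 22810 rows, 64 control probe sets were left out, and 17910 of the other 22746 were kept because their log2 value was at least 4 on at least 4 arrays. Probe sets were named through the platform annotation and, by its Entrez gene numbers, through a RefSeq gene table (assembly TAIR10.1), which was used only for names and for the order of neighbouring loci. The annotation gave 1 gene for 13513 probe sets and several genes for 503. It did not list 8730, which stay unnamed here. Of the probe sets of 1 gene, 13436 matched the RefSeq table and 1580 had a symbol other than the locus. No gene was named from a probe set of several genes.

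Differences were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the log2 values, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. The comparison of nga-deficient arrays (the 4 quadruple mutant and amiR-NGA arrays together, as the series design text groups them) with the arrays labelled wild type used 2 groups. The comparisons of each genotype with wild type, and of the genotypes with each other, came from 1 fit with 3 groups, because 2 arrays per genotype give too little information on spread alone. Tests were two-sided. Standard errors (SE) are the moderated errors of these fits.

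Gene lists, 28 in number with 319 entries, were written before the data were examined and matched by locus. Only 53 entries matched a probe set of 1 gene, and 44 were among the kept probe sets, so the lists cover their pathways poorly. Lists with at least 3 kept members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, a rotation test of a list on its own, were run beside it. A gene with several probe sets was represented in a list by the brightest.

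The genes named in the text were chosen by a rule fixed before the data were examined. It took the 4 NGATHA genes. It then took up to 12 rises and 12 falls, largest first, among probe sets of 1 gene past the threshold with a log2 fold change of at least 1 in size, all 4 nga-deficient arrays beyond every array labelled wild type, and a symbol other than the locus. It further took up to 4 members past the threshold from each list, and up to 6 genes with a symbol in each direction past the threshold between the genotypes. Genes known only by locus, and other genes said to be so, were chosen after their values were seen. Kept list members that did not pass the threshold are also named, outside this rule.

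Agreement between the genotypes was measured as the correlation and covariance of their fold changes. Both use the same 7 controls, so values were simulated 100 times with no effect and the same shared controls, and the controls were also split by odd and even replicate number. Alternatives covered the filter, the scaling, array weights, the eBayes settings, a block for the replicate number, the long-days note, a fold threshold of 2, the set of arrays in the fit and leaving out each array. Only arrays labelled wild type have replicate numbers above 2 or the long-days note. With the replicate block, comparisons with wild type therefore rest on wild-type replicates 1 and 2 alone. With the note as a covariate, fold changes equal those against the wild-type arrays without the note. Added after the data were seen were fits with, as a covariate, the difference between 3-prime and 5-prime actin control probe sets, a sign of RNA degradation, and fits without the 3 arrays on which this difference was above 1.5. Also written after the data were seen was a list of 46 late-pollen genes; 2 further genes were taken out of it before the test but after it was known which genes had kept probe sets, 1 because its values had been seen and 1 as not specific to late pollen.

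The procedures were tested on simulated data with the arrays' spreads and 200 changed probe sets among 17910. For nga-deficient against wild type, 26.0% of changes of 0.50 on the log2 scale, 82.0% of changes of 1.00 and 98.0% of changes of 2.00 were recovered, with 8 false calls. For the quadruple mutant against amiR-NGA these shares were 2.00%, 40.0% and 90.0%, with 5 false calls. With no list changed, camera called at least 1 of the 8 lists in 10.0% of 100 simulations. Probe sets were simulated as independent, while the estimated correlation within a list reached 0.390 (photosynthesis). This share may therefore be too low for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.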

Results

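Expression was measured in inflorescences of 30-day-old Arabidopsis plants to ask which transcripts change when the NGATHA genes are lost. NGA1, NGA2, NGA3 and NGA4 encode related B3-domain transcription factors that act redundantly in the development of the style and stigma. The data comprised 11 arrays: 7 labelled wild type, 2 of the nga quadruple mutant and 2 of amiR-NGA plants, in which an artificial microRNA targets all 4 genes. Across probe sets the mean Pearson correlation was 0.984 between replicates of a group, 0.981 between the quadruple mutant and amiR-NGA, and 0.976 between arrays labelled wild type and nga-deficient arrays. The series design text states 0.985, 0.984 and 0.972 for these averages and groups both genotypes together on that basis. On wild-type replicates 1 and 2 and on quadruple mutant replicate 1, the actin control signal was 2.05 to 2.11 higher on the log2 scale at the 3-prime than at the 5-prime end, against 1.09 to 1.31 on the other arrays.

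The targeted genes were examined first. NGA4 (AT4G01500) and NGA3 (AT1G01030) were lower on all 4 nga-deficient arrays than on any array labelled wild type. NGA4 averaged 6.13 ± 0.22 (SD, n = 7) on the arrays labelled wild type and 4.63 ± 0.19 (n = 4) on the nga-deficient arrays, a 2.82-fold fall (limma log2 fold change -1.49, SE 0.13, adjusted p = 0.000253). NGA3 averaged 5.61 ± 0.22 (n = 7) and 4.28 ± 0.27 (n = 4), the latter near the floor of the values, a 2.51-fold fall (log2 fold change -1.33, SE 0.15, adjusted p = 0.000592). NGA2 (AT3G61970) was lower in the quadruple mutant, by 0.62 on the log2 scale (log2 fold change -0.62, SE 0.12, adjusted p = 0.0201), and in amiR-NGA it averaged 5.40 against 5.34 (log2 fold change 0.06, SE 0.12, adjusted p = 0.844). The test of the difference between the genotypes for NGA2 gave an adjusted p of 0.245.

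NGA1 (AT2G46870) went against the labels. It measured 10.50, 11.003 and 10.51 on wild-type replicates 5, 6 and 7, and 5.65, 5.60, 5.99 and 5.85 on wild-type replicates 1 to 4. On quadruple mutant replicates 1 and 2 it measured 6.95 and 6.50, above the latter 4 wild-type arrays, and on amiR-NGA replicates 1 and 2 it measured 5.02 and 4.88. Its nga-deficient log2 fold change was -2.03 (SE 1.17, adjusted p = 0.328). Because of this disagreement the controls are called the arrays labelled wild type, and every direction below is relative to them. Where the mutant alleles lie relative to the probes is not given in the sources used here, so a retained signal in the quadruple mutant checks nothing about the alleles.

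**Figure D1:**
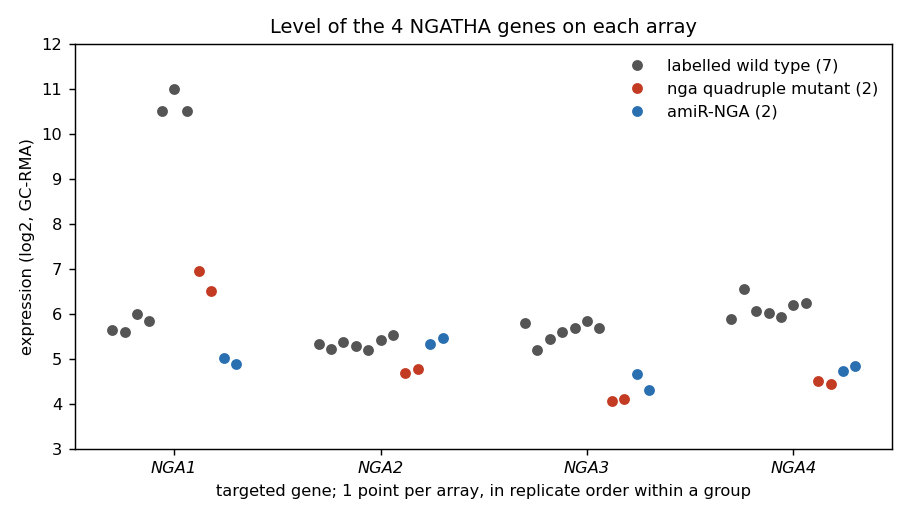
Expression of the 4 NGATHA genes (vertical axis, log2 GC-RMA value) on each of the 11 arrays, 1 point per array, coloured by group. NGA3 and NGA4 were lower on all 4 nga-deficient arrays than on any array labelled wild type, while NGA1 ranged from 5.60 to 11.003 among the arrays labelled wild type.

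Loss of NGATHA activity, with both genotypes in 1 group, was accompanied by more falls than rises. This excess was large in amiR-NGA alone, while in the quadruple mutant alone its direction depended on the fold limit and the scaling, as given below. The falls with a gene symbol included HPR (AT1G68010), hydroxypyruvate reductase of photorespiration, from 11.79 ± 0.18 (SD, n = 7) to 10.55 ± 0.16 (n = 4), a 2.36-fold change (limma adjusted p = 0.000253). SWEET11 (AT3G48740), a sucrose efflux transporter, fell 2.31-fold (log2 fold change -1.21, SE 0.22, adjusted p = 0.0115). MT1C (AT1G07610), a metallothionein, fell 2.50-fold, and SIS (AT5G02020), a salt-induced serine-rich protein, fell 2.74-fold. The rises with a symbol were JAL23 (AT2G39330), a jacalin-related lectin, 4.52-fold, THI2.1 (AT1G72260), a thionin of pathogen defence, 3.42-fold, and APL4 (AT2G21590), a large subunit of the starch-synthesis enzyme ADP-glucose pyrophosphorylase, 2.36-fold. HYH (AT3G17609), a bZIP factor of light signalling, fell 2.06-fold to 4.02, near the floor of the values, and WES1 (AT4G27260), an enzyme that conjugates auxin to amino acids, fell 2.48-fold.

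These genes differed widely in how far the change exceeded the spread between arrays. HPR had an SE of 0.12 on a log2 fold change of -1.24, and it kept its call in every fit that left out an array, as did NGA3, NGA4, SWEET11 and APL4. The calls of SWEET11 and APL4 ended against the wild-type arrays with or without the long-days note and with the note as a covariate, and that of SWEET11 also with the replicate block (adjusted p up to 0.0853 and 0.0617). The log2 fold change was -1.32 (SE 0.26, adjusted p = 0.0159) for MT1C and -1.46 (SE 0.29, adjusted p = 0.0166) for SIS. Without quadruple mutant replicate 2 or amiR-NGA replicate 1 the calls of both ended, with adjusted p of up to 0.0649 and 0.0552. That of MT1C also ended with the replicate block and against the wild-type arrays with or without the long-days note (limma adjusted p up to 0.129). That of SIS ended against the wild-type arrays without the note and with the note as a covariate (up to 0.105). For APL4 the log2 fold change was 1.24 (SE 0.23, adjusted p = 0.0130). JAL23 (2.18, SE 0.52, adjusted p = 0.0359), THI2.1 (1.78, SE 0.43, adjusted p = 0.0376), HYH (-1.04, SE 0.26, adjusted p = 0.0397) and WES1 (-1.31, SE 0.34, adjusted p = 0.0491) lost their calls when some single arrays were left out, with adjusted p of up to 0.101, 0.0971, 0.110 and 0.121. These arrays were all 4 nga-deficient ones and wild-type replicates 2 and 5 for JAL23. For THI2.1 they were the nga-deficient arrays other than amiR-NGA replicate 2, and wild-type replicates 1 to 4. For HYH they were all 4 nga-deficient ones and wild-type replicates 3, 4 and 7. For WES1 they were the nga-deficient arrays other than amiR-NGA replicate 2, and wild-type replicates 1, 3, 4, 5 and 7. The calls of JAL23, THI2.1, HYH and WES1 also ended with the long-days note as a covariate and without the 3 arrays of high actin difference. Over the alternatives their limma adjusted p reached 0.188, 0.190, 0.147 and 0.176.

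Larger changes were seen among genes known here only by locus, which were chosen after their values were seen. AT3G28270 fell most, 11.8-fold, from 7.65 ± 0.46 (SD, n = 7) to 4.08 ± 0.37 (n = 4; limma adjusted p = 1.54e-05), near the floor of the values. AT1G22890, AT1G49500 and AT1G65490 fell 7.31-fold, 7.12-fold and 6.62-fold, and AT4G37560 and AT5G47610 fell 3.96-fold and 3.77-fold. AT5G17540 rose from 4.24 ± 0.11 (n = 7), near the floor of the values, to 6.89 ± 0.46 (n = 4), a 6.26-fold change with the smallest limma adjusted p of all probe sets (1.43e-05). AT3G62040 rose 3.36-fold, AT5G22580 2.52-fold, AT2G27740 2.48-fold and AT5G18840 2.45-fold. AT1G54020, near the floor on the arrays labelled wild type (3.87), averaged 4.54-fold higher, but this combined a log2 fold change of 3.57 in the quadruple mutant with 0.79 in amiR-NGA. Its call (limma adjusted p = 0.0323) ended without wild-type replicate 1, 3, 4 or 5 or either quadruple mutant replicate (adjusted p up to 0.107), and that of AT5G22580 without either quadruple mutant replicate or amiR-NGA replicate 1 (adjusted p up to 0.0610). Calls also ended against the wild-type arrays without the long-days note for AT1G49500 and AT2G27740 (adjusted p = 0.0672 and 0.0701), with it for AT5G22580 (0.171), and with either for AT5G18840 (up to 0.0632).

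In all, 792 of 17910 probe sets passed the limma threshold, 239 higher and 553 lower on the nga-deficient arrays, and 187 of them (61 higher and 126 lower) changed at least 2-fold. Of the 792, 364 had 1 gene, 414 were not listed in the annotation and 14 had several genes. All 4 nga-deficient arrays lay beyond all 7 others, on either side, for 650 of the 792, and for 7.38% of kept probe sets, against 0.606% by chance. The share of lower calls was 69.8%, and 58.0% when each array was centred on its median (320 higher and 441 lower). The count was 229 without amiR-NGA replicate 1, 311 and 337 without quadruple mutant replicates 2 and 1, 416 without wild-type replicate 3, and 256 with the long-days note as a covariate; without the 3 arrays of high actin difference it was 867, of which 532 were among the 792.

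**Figure D2:**
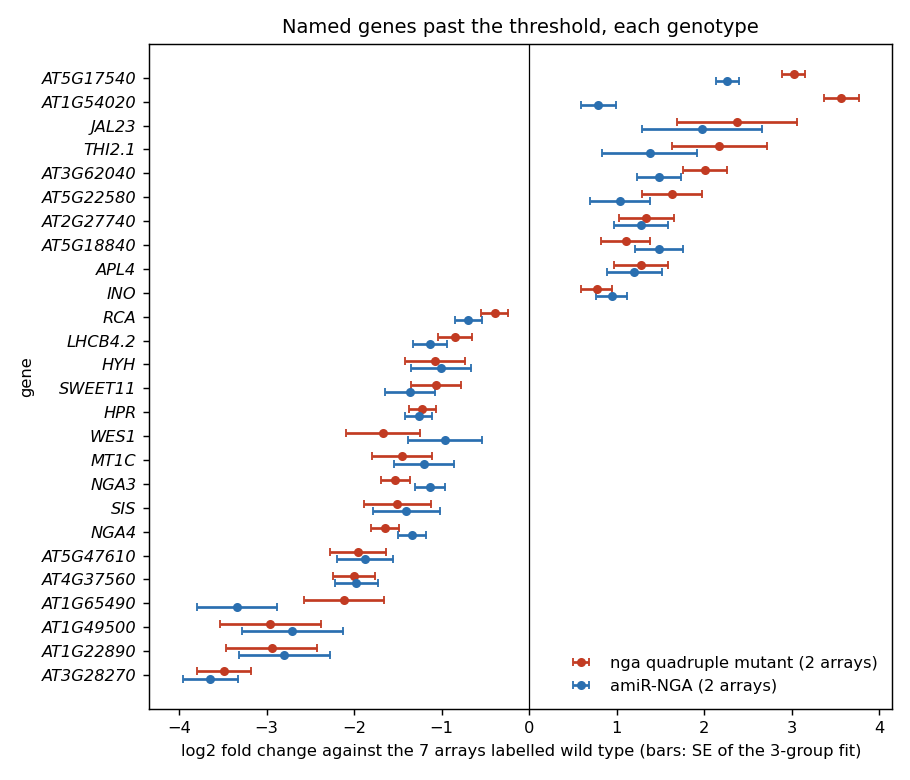
Log2 fold change of named genes against the 7 arrays labelled wild type (horizontal axis), with 1 point per genotype and bars showing the SE of the 3-group fit. Each gene passed the threshold for both genotypes in 1 group, and both points lie on the same side of 0, from AT3G28270 at -3.49 and -3.64 to AT5G17540 at 3.02 and 2.27. For each gene shown all 4 nga-deficient arrays lay beyond every array labelled wild type, for most as a condition of the choice. The shared side is therefore no separate evidence that the genotypes agree.

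Of the 25 entries of the photosynthesis list 3 were kept, and 2 of these fell. LHCB4.2 (AT3G08940), an antenna protein of photosystem II, fell 1.98-fold, from 11.07 ± 0.29 (SD, n = 7) to 10.08 ± 0.18 (n = 4; limma adjusted p = 0.00549), a call that ended against the wild-type arrays without the long-days note (adjusted p = 0.0511). RCA (AT2G39730), Rubisco activase, fell 1.46-fold (adjusted p = 0.0332), a call lost without any 1 of wild-type replicates 3 to 6 or of the 4 nga-deficient arrays (adjusted p up to 0.110). The RCA call also ended with the replicate block and in each fit that used the long-days note (limma adjusted p up to 0.309). LHCB4.1 had a log2 fold change of -0.36 (adjusted p = 0.115). Adjusted over the list alone, all 3 were lower. The camera test of the list gave an adjusted p of 0.00122, and the call was lost with an estimated correlation (adjusted p = 0.0702). Without the 3 arrays of high actin difference the camera adjusted p was 0.00116, and over all alternatives it ran from 0.000665 to 0.143, the highest with a block for the replicate number, which ended the call.

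The organ polarity list, whose 4 kept members were the YABBY genes INO, YAB3 and YAB5 and the class III HD-ZIP gene PHV, was higher on the nga-deficient arrays. INO (AT1G23420), which specifies the outer integument of the ovule, rose 1.81-fold, from 4.72 ± 0.20 (SD, n = 7) to 5.58 ± 0.26 (n = 4; limma adjusted p = 0.00595), and was the member past the threshold over all probe sets. This call ended against the wild-type arrays with the long-days note (adjusted p = 0.0825). YAB5, PHV and YAB3 had log2 fold changes of 0.48, 0.44 and 0.32, with adjusted p of 0.125 or more, and adjusted over the list alone all 4 members were higher. The camera adjusted p was 0.00122, and 0.0259 with an estimated correlation, and the call ended with the replicate block (adjusted p = 0.144). The list of the 4 NGATHA targets was lower (camera adjusted p = 0.000248, 0.0259 with an estimated correlation, and 0.143 with the replicate block), with NGA3 and NGA4 past the threshold and, adjusted over the list alone, the same 2. These are the genes that the genotypes target, so a fall of this list is no finding about a pathway. Of 100 divisions of the 11 arrays into 4 and 7, the real one included, 6 called at least as many lists as the real groups, so chance was not excluded for the number of lists.

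Lists for auxin, the style and the carpel did not pass. Auxin biosynthesis had 0 of 3 kept members past the threshold (YUC2, YUC4 and YUC6, median log2 fold change -0.13, camera adjusted p = 0.795). Auxin response had 1 of 6, WES1, with a median of -0.01 and a mean of -0.41 (camera adjusted p = 0.370). The related GH3.3 had a log2 fold change of -1.35 (SE 0.38, adjusted p = 0.0603), and adjusted over the list alone 2 of the 6, WES1 and GH3.3, were lower. These 2 were bright on the arrays labelled wild type (10.36 and 9.59). IAA20, IAA29 and IAA30 averaged 4.15, 4.14 and 4.71 there, near the floor of the values, where a fall could hardly be seen. The median therefore does not show that auxin response was unchanged. The lists of style, stigma and transmitting tract regulators (SPT, ALC and CES, median -0.04, camera adjusted p = 0.989), of carpel and fruit regulators (JAG, NUB and SEU, median -0.43, adjusted p = 0.532) and of flavonoid genes (median 0.23, adjusted p = 0.133) had 0 of 3 members each past the threshold. The flavonoid list passed without wild-type replicate 6 (camera adjusted p = 0.0290). Adjusted over the list alone, NUB and SEU were lower and JAG higher (limma adjusted p over all probe sets 0.0649, 0.105 and 0.0748). For the 11 lists with 1 or 2 kept members no list test was run, and INO in the ovule list was the member past the threshold; the other 9 lists had 0 kept members.

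Each genotype was then set against the arrays labelled wild type. In the quadruple mutant NGA4, HPR, INO, LHCB4.2, MT1C, SIS, APL4, THI2.1 and WES1 were among 747 probe sets past the limma threshold, 348 higher and 399 lower. THI2.1 rose 4.52-fold, with 10.81 and 8.81 on the quadruple mutant replicates, and WES1 had a log2 fold change of -1.66, with 7.87 and 9.52. The count rested on quadruple mutant replicate 1, on which the actin difference was high: it was 39 without that array, 343 and 427 without wild-type replicates 3 and 4, and 124 without the 3 arrays of high actin difference. Median centring gave 349 higher and 264 lower. Of the 747 probe sets, those that changed at least 2-fold were 226 higher and 152 lower, so the quadruple mutant alone showed no steady excess of falls.

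In amiR-NGA 167 probe sets passed, 21 higher and 146 lower. They included NGA3, NGA4, HPR (log2 fold change -1.26, SE 0.16, limma adjusted p = 0.00452), INO (0.95, SE 0.18, adjusted p = 0.0306), LHCB4.2 (-1.13, SE 0.20, adjusted p = 0.0235), AT5G17540 (2.27, SE 0.13, adjusted p = 1.63e-05) and AT3G28270 (-3.64, SE 0.31, adjusted p = 0.000692). The amiR-NGA log2 fold changes of SWEET11 (-1.36, adjusted p = 0.0524) and APL4 (2.30-fold, adjusted p = 0.117) did not pass. The count was 5 without either amiR-NGA replicate, 78 and 88 without wild-type replicates 5 and 3, and 420 without the 3 arrays of high actin difference. A count past the threshold in 1 genotype and not in the other does not show that the genotypes differ.

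The fold changes of the genotypes were correlated across probe sets (r = 0.598), where probe sets are not independent replicates. Simulated groups with no effect and the same controls gave 0.222. The covariance was 0.0910 against 0.0130 simulated, a difference of 0.0780 that estimates the shared part. With the controls split between the comparisons the correlation was 0.507 and 0.527, and the covariance 0.0808 and 0.0839. Calls shared by both genotypes numbered 17 higher and 78 lower, a count that the same controls raise and for which no chance value is given. The correlation was 0.346 without amiR-NGA replicate 1 and 0.462 without quadruple mutant replicate 2.

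The quadruple mutant and amiR-NGA were compared with each other to ask whether the genotypes that the study grouped differ. Most of the probe sets that differed were higher in the quadruple mutant, and for the named genes amiR-NGA lay within 0.41 of the arrays labelled wild type on the log2 scale, AT1G54020 (0.79) apart. ECS1 (AT1G31580), a cell-wall protein gene, was 14.2-fold higher, at 9.71 ± 0.68 (SD, n = 2) against 5.89 ± 0.26 (n = 2; limma adjusted p = 0.0167). QQS (AT3G30720), an orphan gene that affects starch content, was 5.47-fold higher (adjusted p = 0.000842), a fold that is not exact because it averaged 3.64 in amiR-NGA, near the floor of the values. 2A6 (AT1G03410) was 4.98-fold higher on 1 probe set (adjusted p = 0.000689), while its other probe set had a log2 difference of 0.67 (adjusted p = 0.627). LCR66 (AT1G61070), a small cysteine-rich defensin-like protein, was 4.37-fold higher, RSU1 (AT3G48130) 2.95-fold and ATB2 (AT1G60710) 2.82-fold. RSU1 averaged 4.26 in amiR-NGA, near the floor of the values, so its fold is not exact either.

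The lower transcripts in the quadruple mutant included neighbours of the mutated genes. AT3G61960, 2 loci from NGA2 in the annotated order, averaged 3.52 ± 0.26 (SD, n = 2) in the quadruple mutant against 7.57 ± 0.07 (n = 2) in amiR-NGA, 16.6-fold lower (limma adjusted p = 1.48e-05), and AT3G61950, 3 loci from NGA2, was 3.87-fold lower (adjusted p = 0.00130). ARV2 (AT4G01510), a sterol homeostasis gene 2 loci from NGA4, was 4.68-fold lower (adjusted p = 0.00191). In the quadruple mutant these 3 genes averaged 3.52, 3.43 and 3.32, below the filter value of 4 and near the floor of the values, so that the sizes of their folds are not exact. AT1G10110 was lower (log2 difference -1.66, adjusted p = 0.000137). The 3 genes known by locus were chosen after their values were seen. In all, 24 probe sets passed, 18 higher and 6 lower. The count was 2 with only the 4 arrays compared in the fit, 14 and 13 without quadruple mutant replicate 1 or amiR-NGA replicate 2, and 179 without quadruple mutant replicate 2, and the call of ECS1 ended without quadruple mutant replicate 1 or either amiR-NGA replicate (adjusted p up to 0.169), without the 3 arrays of high actin difference and against the wild-type arrays without the long-days note (adjusted p up to 0.225), though its log2 difference was 3.83 (SE 0.56) with all arrays and 4.30 (SE 0.67) without quadruple mutant replicate 1. The call of ATB2 ended without quadruple mutant replicate 1 or amiR-NGA replicate 2 (adjusted p up to 0.104) and against the same wild-type arrays; its log2 difference was 1.49 (SE 0.19) with all arrays and 1.48 (SE 0.24) without quadruple mutant replicate 1. With only the 4 arrays in the fit, or with the replicate block, the calls of ECS1, QQS, 2A6, LCR66, RSU1, ATB2, ARV2, AT1G10110 and AT3G61950 ended (adjusted p up to 0.313), while AT3G61960 kept its call (adjusted p up to 0.0363).

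**Figure D3:**
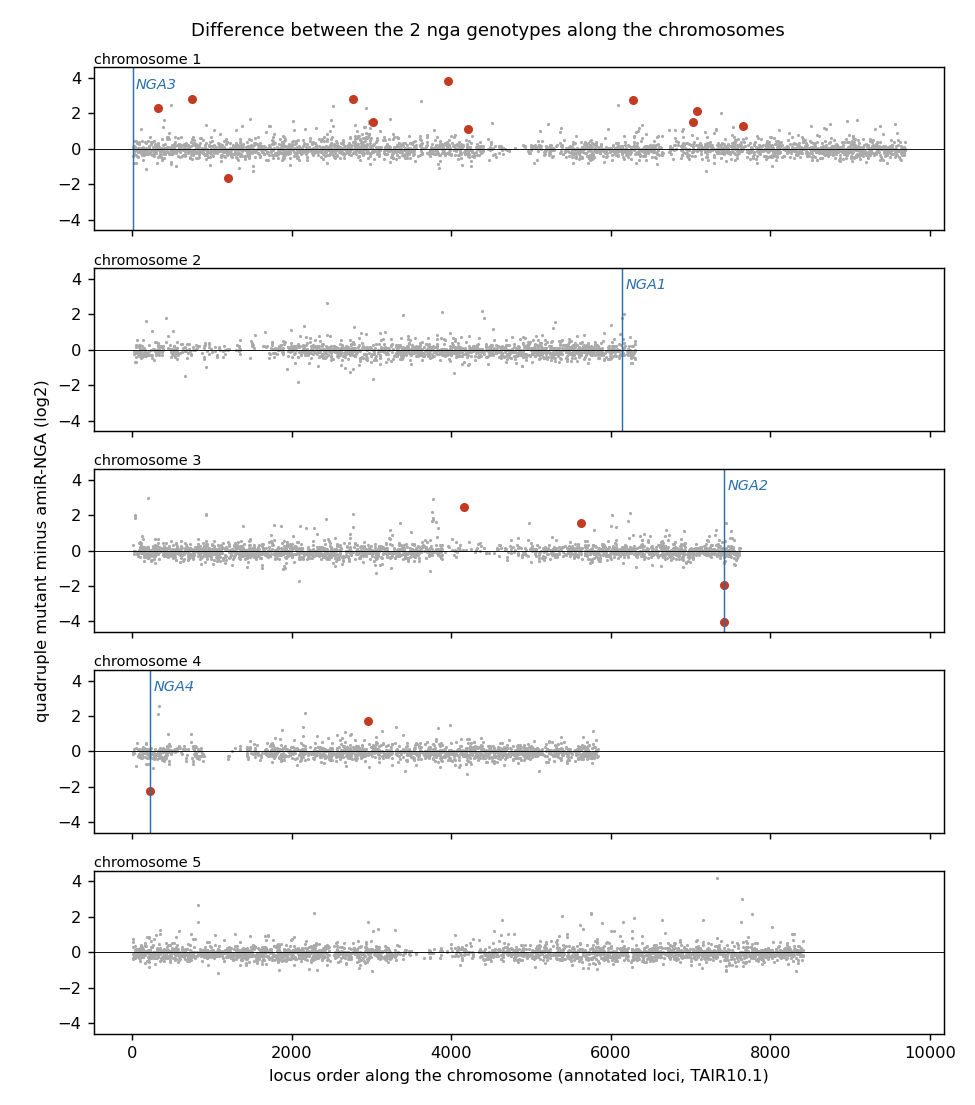
Difference between the quadruple mutant and amiR-NGA (vertical axis, log2) for each tested locus in its order along the 5 chromosomes (horizontal axis, locus number in the TAIR10.1 annotation). Red points are the 17 located loci past the threshold, 11 of them on chromosome 1, and blue lines mark the 4 NGATHA loci; AT3G61960 beside NGA2, which is near the floor of the values in the quadruple mutant, lies at -4.05.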

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

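Chosen only after the results were seen were the tests of RNA quality or distinct RNA, the long-days note, mislabelled arrays and pollen; the test of loci near the NGATHA genes was planned before the data were examined, and that of segments of chromosome 1 was set before its own result but after the calls on that chromosome had been noticed.

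Differences between the quadruple mutant and amiR-NGA passed the limma test for 11 named genes, with log2 differences of 3.83 for ECS1, 2.45 for QQS, 2.32 for 2A6, 2.13 for LCR66, 1.56 for RSU1, 1.49 for ATB2, 2.78 for AT1G54020, -2.23 for ARV2, -1.66 for AT1G10110, -4.05 for AT3G61960 and -1.95 for AT3G61950. A distinct RNA on quadruple mutant replicate 1 is argued against for 23 of the 24 probe sets, which were among the 28 of 179 probe sets called on replicate 1 alone that passed on replicate 2 alone against both amiR-NGA and wild type (adjusted over the 179), and it stays open for 1, that of AT1G65280. The 24 were called with both replicates, so the share of 23 among them was raised by selection. The argument rests on the 28, chosen on replicate 1 and tested on replicate 2, though against the same amiR-NGA and wild-type arrays. Variants or segments linked to the mutant alleles may account for 3 loci, AT3G61950, AT3G61960 and ARV2: 0.773% of the 388 tested loci within 200 loci of an NGATHA gene were past the threshold, beyond random placements of such windows (permutation p = 0.0267), while the other 14 located loci lie outside the windows. Of the 17 located loci 11 are on chromosome 1, which holds 26.3% of tested loci. Of the 118 neighbouring loci there, 5.93% had an unadjusted p under 0.05 against a median of 8.47% in random draws (permutation p = 0.914). Short segments of that chromosome that change many neighbouring transcripts are therefore argued against. Longer segments, and segments that change few transcripts, stay open, because they need not raise this share above random draws. A mutation or insertion outside these windows, a difference in the seed stock and an effect of the genotype itself stay open and were not tested.

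NGA1 differed among the arrays labelled wild type, with a largest gap of 4.51 on the log2 scale between neighbouring arrays, the second largest of all kept probe sets. RNA quality is argued against, because NGA1 spanned 5.15 among the 5 arrays labelled wild type with a low actin difference. The long-days note alone does not account for the gap, since NGA1 spanned 5.36 among the 4 arrays without the note. That span rests on wild-type replicate 1 (5.65), the only low array without the note, and its labels state no day length. Day length itself therefore stays open. The arrays with the note were all low in NGA1, so fits that used the note also divided the arrays largely by NGA1 level. Nga-deficient arrays labelled wild type are argued against, because the lowest NGA4 level among the arrays labelled wild type lay 1.05 above the highest nga-deficient one. Extra NGA1 sequence, such as a transgene, stays open, and no biological explanation was tested.

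Quadruple mutant replicate 1 stood apart from replicate 2. Its actin difference of 2.11 and its median of 6.15 over all probe sets lay far from those of the other nga-deficient arrays. RNA quality stays open: across probe sets the difference of replicate 1 from 2 correlated at r = 0.271 with that of wild-type replicates 1 and 2 from the other arrays labelled wild type, a value that the prediction left undecided. More maturing pollen on replicate 1 may contribute, since the 13 late-pollen genes with kept probe sets, the most abundant of them ACT11 at 9.27 and TUA1 at 8.37, were all higher on it than on replicate 2, by a median of 0.82 (permutation p = 0.0001, the smallest that 10000 draws can give). This p treats the genes as independent and compares 1 array with 1 array, so it does not measure spread between samples. On the arrays labelled wild type ACT11 reached 9.20 and TUA1 8.45. The 13 genes were higher by a median of 0.31 on wild-type replicates 1 and 2 than on the other arrays labelled wild type. On quadruple mutant replicates 1 and 2 and amiR-NGA replicates 1 and 2 their medians lay 0.89, 0.03, 0.33 and -0.22 from the wild-type mean. Both amiR-NGA replicates had a low actin difference (1.25 and 1.09), so these genes also varied between arrays of similar RNA quality by this measure. Quadruple mutant replicate 1 differed from replicate 2 in both the actin difference and the pollen genes. For that array RNA quality and pollen cannot be told apart.

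Single arrays far from the rest of their group were found in 7 of 102 groups examined, and chance flags about 1 in 20, or 5.1. WES1 measured 7.87 and AT5G22580 10.72 on quadruple mutant replicate 1, IRX15-L measured 5.29 on amiR-NGA replicate 2, and AT1G49500 measured 6.69 on wild-type replicate 7. The nga-deficient group of 4 mixes both genotypes. The control probe set U12639 measured 3.78 on wild-type replicate 2.

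The same control probe set, which entered no comparison, averaged 7.83 on the quadruple mutant arrays and did not exceed 3.78 on any other array; the sequence it detects is not given in the sources used here.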

How the results depend on the processing

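The fits with the actin difference as a covariate and without the 3 arrays on which it was high were chosen after the data were seen. The correlation between genotypes was positive in all fits tried. Single genes were followed for 48 named genes, which leaves out the other list members that did not pass the threshold. Of these 48 all except NGA1 kept their direction. For 624 of 756 of their values the side of the threshold stayed the same and for 130 it did not. The auxin biosynthesis and style lists, which did not pass, turned direction in some alternatives. NGA1 turned to 0.21 with the replicate block and 0.0228 against the wild-type arrays with the long-days note. Calls of named genes ended against the wild-type arrays with the long-days note (JAL23, THI2.1, APL4, MT1C, WES1, SWEET11, INO, RCA, AT1G54020, AT5G22580, AT5G18840, ndhA, LHCB4.3, NdhN, NdhS, NdhL, NDB3, HIS1-3, OCT1), against those without it (THI2.1, APL4, SIS, MT1C, WES1, SWEET11, HYH, LHCB4.2, RCA, ECS1, ATB2, AT1G54020, AT2G27740, AT5G18840, AT1G49500, ndhA, NdhN, NdhS, NdhL, CSLA01, NDB3, IRX15-L, HIS1-3, OCT1), with the note as a covariate (JAL23, THI2.1, APL4, SIS, WES1, SWEET11, HYH, RCA, AT1G54020, NdhN, NdhS, NdhL, CSLA01, NDB3, IRX15-L, HIS1-3, OCT1), without the 3 arrays of high actin difference (JAL23, THI2.1, WES1, HYH, ECS1, AT1G54020, NdhN, NDB3, IRX15-L, HIS1-3, OCT1), with the replicate block (MT1C, WES1, SWEET11, RCA, ECS1, QQS, 2A6, LCR66, RSU1, ATB2, ARV2, AT1G54020, ndhA, LHCB4.3, NdhN, AT1G10110, AT3G61950, NDB3, HIS1-3, OCT1), with only the arrays compared (ECS1, QQS, 2A6, LCR66, RSU1, ATB2, ARV2, AT1G10110, AT3G61950), with no filter (WES1, OCT1), with median centring (NdhS, NdhL, OCT1), with quantile normalization (NdhL) and with array weights (AT1G54020), with adjusted p of up to 0.313; a fold change of at least 2 as well ended those of INO, LHCB4.2, RCA, ndhA, LHCB4.3, NdhN, NdhS and NdhL by construction. The cause of a change was not tested unless given. Leaving out an array moved the count of probe sets from 229 to 973 for nga-deficient, 39 to 963 for the quadruple mutant, 5 to 212 for amiR-NGA and 13 to 179 between genotypes, and the correlation from 0.346 to 0.716; the lone array of a genotype is then assumed to vary like the others, and fewer arrays lower the power. Over these same 4 comparisons in that order, the wild-type arrays with the long-days note gave 229, 204, 48 and 13, those without it 141, 132, 35 and 12, and the note as a covariate 256, 236 and 81 for the first 3. Array weights gave 2977 for nga-deficient, 1650 for amiR-NGA and 45 between genotypes. A fold change of at least 2 as well, which by construction removes calls, gave 187, 378 and 96. The stricter filter, which tests fewer probe sets and leaves fewer lists of at least 3 members, gave 12 between genotypes and 1 list, and only the arrays compared gave 2 between genotypes. With the replicate block the counts were 1932, 252, 859 and 2, with 0 lists by camera (2 of 8 at an unadjusted p under 0.05) and a correlation of 0.780. In this fit the only controls in effect were wild-type replicates 1 and 2, both of high actin difference, since higher replicate numbers occur only in wild type. Lost calls there may reflect these fewer controls. The labels do not say whether replicate numbers mark shared batches. Replicate 1 minus 2 correlated at 0.285 between quadruple mutant and amiR-NGA, -0.0740 between quadruple mutant and wild type and -0.113 between amiR-NGA and wild type. A batch shared by replicate number is therefore not excluded, least of all between the 2 nga genotypes. The actin difference as a covariate gave 1898 and 1685 for nga-deficient and the quadruple mutant, and leaving out the 3 arrays gave 124 for the quadruple mutant and 420 for amiR-NGA. Dim probe sets near the floor limit what can be seen: 4836 of 22746 were not kept.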

Other observations

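The tests of NDH, antenna and plastid-encoded genes, and the genes singled out for changes that did not separate every array, were chosen after the data were seen; the lists and divisions were planned. Of the 12 kept genes with an ndh symbol, which encode subunits of the chloroplast NDH complex, 4 were lower on the nga-deficient arrays past the limma threshold, and the median log2 fold change of the 12 was -0.51; no list test was run on them. These were ndhA, encoded in the chloroplast (1.85-fold lower, adjusted p = 0.00937), and the nuclear genes NdhN (1.74-fold, adjusted p = 0.0307), NdhS (1.56-fold, adjusted p = 0.0322) and NdhL (1.83-fold, adjusted p = 0.0393). NdhL lost its call under quantile normalization and median centring, and NdhS under median centring. Calls also ended against the wild-type arrays with the long-days note for all 4 and LHCB4.3, against those without it for all 4, with the note as a covariate for NdhN, NdhS and NdhL, with the replicate block for ndhA, NdhN and LHCB4.3, and without the 3 arrays of high actin difference for NdhN (adjusted p up to 0.157, and up to 0.0864 for ndhA). With single arrays left out, calls ended for NdhN without any nga-deficient array, for NdhS without any of these or wild-type replicate 3, 4 or 5, for NdhL without quadruple mutant replicate 2, either amiR-NGA replicate or wild-type replicate 2, 3, 5 or 6, and for LHCB4.3 without quadruple mutant replicate 2 or amiR-NGA replicate 1 (adjusted p up to 0.125). The antenna gene LHCB4.3 fell 1.67-fold (adjusted p = 0.0186). Of the 66 plastid-encoded genes with kept probe sets 60 were lower, with a median of -0.27, and 1 passed the threshold. Camera gave p = 9.62e-06 for them at the preset correlation and p = 0.0921 with an estimated correlation. Without the 3 arrays of high actin difference 60 were again lower (median -0.38, p = 0.0898 with an estimated correlation).

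Further genes changed at least 2-fold past the limma threshold without separating every array. The cell-wall genes CSLA01, a glucomannan synthase, and IRX15-L, which acts in xylan synthesis, rose 3.13-fold and 2.28-fold (adjusted p = 0.0156 and 0.0273), with 3 of 4 nga-deficient arrays above all others. NDB3, a mitochondrial NAD(P)H dehydrogenase, and OCT1, a carnitine transporter, rose 2.16-fold and 2.61-fold (adjusted p = 0.0268 and 0.0446). HIS1-3, a drought-inducible linker histone, fell 4.81-fold (adjusted p = 0.0379), to 3.76 in the quadruple mutant, near the floor of the values. Each call ended without quadruple mutant replicate 2, and all but that of CSLA01 also without quadruple mutant replicate 1 or amiR-NGA replicate 1. Wild-type replicate 3 did so for IRX15-L, replicates 1, 3, 4 and 6 for HIS1-3, and all but replicate 5 for OCT1, with adjusted p of up to 0.0503 for CSLA01, 0.0914 for IRX15-L, 0.0925 for NDB3, 0.135 for OCT1 and 0.118 for HIS1-3. Each also ended against the wild-type arrays without the long-days note and with the note as a covariate, and all but that of CSLA01 without the 3 arrays of high actin difference. Those of NDB3, HIS1-3 and OCT1 ended against the wild-type arrays with the note and with the replicate block, and that of OCT1 with no filter and with median centring (adjusted p up to 0.198).

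Lists with fewer than 3 kept members gave these values. Adjusted over the list alone, ARR15 and RR16 were higher in the cytokinin list and INO in the ovule list. In a list of 1 kept member this adjustment changes nothing, and the unadjusted p was under 0.05 for AT3G11580, AT5G45880, AT5G44630 and GI, as for 4013 of all 17910 probe sets. The pollen gene AT5G45880 had a log2 fold change of 1.23 (limma adjusted p = 0.187) and measured 11.59 and 10.40 on quadruple mutant replicates 1 and 2, 10.49 and 8.46 on amiR-NGA replicates 1 and 2, and at most 10.06 on the arrays labelled wild type. The terpene synthase gene AT5G44630 had 0.89 (adjusted p = 0.0702), the cytokinin response regulators ARR15 and RR16 had 0.28 and 0.65 (adjusted p of 0.178 or more), the clock gene GI had 0.50 (adjusted p = 0.128) and SHI had -0.36 (adjusted p = 0.226). The tapetum genes AMS and AT5G07230 had -0.15 and -0.11, the heat shock genes ATHSP22.0 and AT5G48570 had -0.11 and 0.46, the NGATHA-like gene AT3G11580 had -0.50, PRL had 0.13, SHN3 had 0.40 and SPL had -0.03, with adjusted p from 0.134 to 0.960.

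Other divisions of the 11 arrays into 4 and 7 were fitted to see whether chance gives as much as the real groups. For the number of probe sets past the threshold, 1 of 100 divisions, the real one, gave 792, and the highest of the others gave 1. A chance division of these arrays is therefore argued against for this count. Differences between plantings are not excluded by it, because the labels do not say whether replicates came from separate plantings. For the number of lists, 6 of 100 divisions gave at least the 3 of the real groups, and the highest of the others gave 4, so chance is not excluded for that number.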
